A study of Arabidopsis thaliana with 15 samples.

How the data were processed

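RNA sequencing of inflorescence meristems was analysed in 15 libraries, 1 per sample, in 6 groups set by the labelled genotype and treatment: wild type (n = 2), ap1-1 (n = 3), ap1-1 with a microRNA against STM and BP under the AP1 promoter (n = 2), 35S::STM-GR with DEX (n = 3), 35S::STM-GR with mock spray (n = 3) and wild type with DEX (n = 2). Per the labels' protocols, mock spray was 0.02% Silwet, DEX spray added 10 µM dexamethasone, and sampling followed after 5 h. The labels give wild type, ap1-1 and the microRNA line no treatment. They state no batch, date or sowing, and nothing in them says how far the replicates were grown apart, so p-values here measure the spread between these samples. The study's design text names the allele ap1-4 where the sample labels name ap1-1, and the labels' name is used. The labels do not say whether the microRNA line and the ap1-1 plants came from the same stock.

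Gene counts were made by the authors with TopHat2 2.0.6 and HTSeq 0.62 against TAIR10, per the submitters' processing notes, and 1 table of counts per library was deposited. A table of normalized signal over all libraries was also deposited by the authors, made with DESeq2 per the submitters' processing notes. Each of its values equals the count divided by the library's median-of-ratios size factor, as checked against the counts in all 15 columns. The tests started from the counts, and the normalized values served only as an alternative input. The counts covered 28775 genes, while 5 entries naming no gene (reads outside genes, ambiguous reads and the like) stayed out of library sizes and tests. They made up 5.49% to 6.63% of reads.

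Gene names came from the RefSeq table of the TAIR10.1 assembly, which held 28009 of the genes counted, of which 21599 were among the genes tested. The order of genes along a chromosome was taken from their locus identifiers. The strand setting of the counting is not stated, so counts of overlapping or antisense genes and of near-identical copies (VGD1 and VGDH1, AGL71 and AGL72, LHCB1 genes, histone genes, GSTF7) are less certain.

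Library totals were 18717248 to 26539358 gene counts. Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 6 groups with a minimum count of 10, which kept 21716 genes, TMM normalization, and quasi-likelihood F tests in 1 fit of all 15 libraries. Benjamini-Hochberg adjustment ran over all genes tested within a comparison, and an adjusted p under 0.05 made a call. The biological coefficient of variation was 9.85%. CPM are edgeR's, scaled by TMM library size, and log2 CPM use a prior count of 2. The SE of a log2 fold change is its size over the square root of F. The comparisons were the microRNA line against ap1-1 (silencing), DEX against mock in 35S::STM-GR (induction), DEX-sprayed against unsprayed wild type, the difference between these 2 DEX responses, and ap1-1 against wild type. Overlaps of calls were tested with Fisher's exact test, one-sided, over genes tested, with Benjamini-Hochberg adjustment. It counts genes as independent draws, which genes that vary together are not, so its p-values overstate the evidence. A fold change against a group with 0 counts is given as a minimum over a floor of 3 counts for the group. Where that group had few counts the ratio has a 95% interval, and both cover counting error only.

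Before the files were read, 23 gene lists were fixed: KNOX class I, BELL and KNOX class II, floral meristem identity and flowering, floral organ identity, organ boundary, meristem maintenance, lateral organ and polarity, TCP, cytokinin turnover, type-A response regulators, gibberellin, auxin response, auxin transport, cell cycle, lignin, stem with xylem and phloem, circadian clock, touch and stress, jasmonate, carpel and ovule, mature pollen, tapetum and pollen wall, and photosynthetic tissue. Lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The genes to name were also set by rule: STM, KNAT1, KNAT2, KNAT6, AP1, LFY and UFO, up to 6 genes that rose and 6 that fell with the largest log2 fold change, and up to 4 members of each list with the lowest adjusted p. The 6 and 6 needed an adjusted p under 0.05, an average log2 CPM of at least 1, a symbol and, outside the differing response, no overlap between the libraries compared. From these the report mainly names genes that kept the call in every alternative followed for single genes.

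The differential tests and camera were run on simulated counts with known changes, with the same spread per gene in every group. In the data, chi-square per gene between 2 replicates was 14.4 to 32.6 in unsprayed wild type and ap1-1. It was 3.17 to 7.79 in the other groups, so the simulated rates may not hold for comparisons with unsprayed wild type or ap1-1. The fit of all libraries gives each gene 1 spread for every group, so p-values in those comparisons may be too small. edgeR recovered, at 1.5-fold, 2-fold and 4-fold, 43.9%, 78.5% and 95.4% for silencing (21489 genes, 7 false calls), 53.0%, 81.0% and 97.0% for induction (21467 genes, 6 false calls), 41.8%, 83.6% and 92.3% for DEX in wild type (21485 genes, 8 false calls), 14.9%, 71.2% and 87.9% for the differing response (21473 genes, 8 false calls) and 53.0%, 88.1% and 93.9% for ap1-1 against wild type (21475 genes, 5 false calls). Alternatives were DESeq2 1.42.0, limma-voom, size factors in place of TMM, no filter or a stricter filter, a minimum change of 2-fold, an adjusted p of 0.01, a replicate block by the number in the title or in the description, only the groups compared in the fit, the authors' normalized values with limma, and leaving out each library in turn. The DEX-sprayed wild type carries other replicate numbers in its titles than in its descriptions. Single genes were followed only under DESeq2, size factors, no filter, the block by title number, only the groups compared and each library left out. Where 1 library was left in a group, it was assumed to vary like the other groups. Induction was also tested against DEX-sprayed wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, transcript forms and sequence variants were not analysed here.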

Results

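Gene expression was measured by RNA sequencing in 15 libraries of inflorescence meristem tissue from Arabidopsis thaliana plants of the Ler background, grown for 6 weeks at 21 °C. Unsprayed plants were wild type (n = 2), the floral mutant ap1-1 (n = 3), and ap1-1 plants with a microRNA against SHOOT MERISTEMLESS (STM) and BREVIPEDICELLUS (BP, listed as KNAT1) driven by the AP1 promoter (n = 2), called the microRNA line. Sprayed plants carried 35S::STM-GR, in which STM is fused to the glucocorticoid receptor and enters the nucleus on dexamethasone (DEX), and received 10 µM DEX (n = 3) or mock solution (n = 3). Wild type sprayed with DEX (n = 2) completed the set, and sprayed plants were sampled after 5 h. The wild type it is compared with was unsprayed, so spray and DEX were not separated there. The libraries held 18717248 to 26539358 gene counts, and 21716 genes were tested. On the first principal component of log2 CPM, with 57.0% of the variance, the microRNA libraries lay at -114 and -113 and the other libraries between -31.7 and 54.9. Values are mean CPM (counts scaled to library size) ± SD, and log2 fold changes ± SE. Calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and gene lists were tested with camera. List counts cover all tested members, and only some of the called members are named.

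The microRNA line was compared with ap1-1 to ask what follows when STM and BP are lowered where AP1 is active. STM (AT1G62360), the homeobox gene that keeps shoot meristems undifferentiated, fell to 31.5 ± 0.528 CPM (n = 2) against 47.9 ± 3.35 CPM (n = 3), with log2 fold change -0.61 ± 0.08, edgeR adjusted p = 1.49e-04. KNAT1 (AT4G08150), the other target, was at 40.6 ± 1.13 CPM (n = 2) against 53.6 ± 11.7 CPM (n = 3) and was not called (log2 fold change -0.41 ± 0.14, edgeR adjusted p = 0.0701). DESeq2 did call KNAT1 lower (adjusted p = 0.0493), and so did edgeR without ap1-1 replicate 2 (-0.57 ± 0.11, adjusted p = 0.00280). The related genes KNAT2 (0.14 ± 0.12) and KNAT6 (0.03 ± 0.12) and the flower meristem regulators LFY (0.14 ± 0.15) and UFO (0.12 ± 0.33) were not called either. Transcripts of AP1 (AT1G69120), whose mutant allele both lines carry, rose from 88.3 ± 1.90 to 124 ± 2.11 CPM (log2 fold change 0.49 ± 0.07, edgeR adjusted p = 1.82e-04). In all, 1057 genes rose and 2475 fell, and 118 of the first and 1332 of the second changed at least 2-fold.

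The strongest rises were those of NRPD1B (3.23 ± 0.18), RVE2 (2.89 ± 0.17), DML1 (2.51 ± 0.10), DFR (2.50 ± 0.41), NAT7 (2.23 ± 0.20) and JMJD5 (2.08 ± 0.15) (edgeR adjusted p of at most 6.61e-04). NRPD1B encodes the largest subunit of RNA polymerase V, DML1 (ROS1) a DNA demethylase, and DFR the dihydroflavonol reductase of anthocyanin synthesis. In the microRNA line, ap1-1 and wild type, in this order, NRPD1B was at 131, 14.0 and 113 CPM, DML1 at 146, 25.8 and 168 and NAT7 at 5.73, 1.21 and 2.67, so each was lowest in ap1-1, the reference here. The strongest falls were in genes with 0 counts in the microRNA line, among them EXPB5. The others were set against a floor of 3 counts over its libraries. CYP76C3 was at least 120.5-fold lower, RALFL25 at least 91.7-fold, GH9B11 at least 50.7-fold and DELTA-VPE at least 48.9-fold. GPAT5 had 1 count there and was 1082-fold lower, with a 95% counting interval of 194 to 42739.

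Flower organ genes were among those that fell. In the floral organ identity list 7 of 14 fell (8 fell adjusted over the list alone). Camera gave adjusted p = 0.00230, and adjusted p = 0.248 with an estimated correlation. Falling members included AG (-0.73 ± 0.10), SHP1 (-0.95 ± 0.14), SHP2 (-1.06 ± 0.14), PI (-0.51 ± 0.07) and STK (-0.91 ± 0.15), MADS-box genes of stamens, carpels and ovules. In the carpel and ovule list, which shares SHP1, SHP2, STK and CRC with it, 5 of 9 fell (the same number adjusted over the list alone). This list had camera adjusted p = 0.00268, and adjusted p = 0.268 with an estimated correlation. All 3 mature pollen genes fell, VGD1 (-1.76 ± 0.16), VGDH1 (-4.08 ± 0.44) and PPME1 (-2.31 ± 0.26), the same number adjusted over the list alone. Its camera adjusted p was 3.99e-04, and adjusted p = 0.248 with an estimated correlation. VGD1 and VGDH1 are near-identical copies that can share reads. The tapetum and pollen wall list had 0 of 15 in edgeR, 1 lower in DESeq2 and in limma-voom, 7 at an unadjusted p under 0.05, with a median log2 fold change of 0.12.

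Some genes of the lateral organ, flowering and cell cycle lists rose. In the lateral organ and polarity list 6 of 17 rose (the same number adjusted over the list alone). The camera test gave adjusted p = 3.99e-04, and adjusted p = 0.268 with an estimated correlation. Among them were ATHB8 (0.54 ± 0.08) and AS1 (0.50 ± 0.07), a vascular homeobox gene and a repressor of KNOX genes in leaves. In floral meristem identity and flowering 5 of 18 rose and 2 fell (the same number adjusted over the list alone). As a list it had camera adjusted p = 0.0488, and adjusted p = 0.421 with an estimated correlation. Its risers included the flowering regulators SVP (0.77 ± 0.14), AGL24 (0.75 ± 0.13) and BOP2 (0.65 ± 0.11). In the cell cycle list 3 of 11 rose (5 rose adjusted over the list alone), namely KN (0.31 ± 0.08), CYCB1;2 (0.30 ± 0.08) and CYCB1;1 (0.39 ± 0.11). In camera the adjusted p was 0.00230, and adjusted p = 0.268 with an estimated correlation. All 3 lost the call without either microRNA library, with edgeR adjusted p of 0.0598 to 0.238.

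Among genes of the circadian clock CCA1 (-1.88 ± 0.17), PRR7 (-0.75 ± 0.10) and PRR9 (-2.32 ± 0.32) fell (edgeR adjusted p of at most 1.54e-04). LHY fell too, and was at 1.16 ± 0.0657 against 4.63 ± 1.02 CPM (edgeR adjusted p = 4.94e-05). In the clock list 1 of 11 rose and 6 fell (3 rose and 6 fell adjusted over the list alone). Camera gave adjusted p = 0.0119, and adjusted p = 0.268 with an estimated correlation. The riser was FKF1 (0.47 ± 0.08), named after its values were seen, and RVE2, related to CCA1 and outside the list, rose as given above. Among single genes, the stem cell gene WUS (-0.95 ± 0.12) and the growth regulators TCP1 (-1.93 ± 0.17) and BRC1 (-1.49 ± 0.23) fell (edgeR adjusted p of at most 3.75e-04). The gibberellin-inactivating GA2OX1 (-1.59 ± 0.18) and GA2OX2 (-1.01 ± 0.11) fell, as did the auxin-responsive IAA19 (-0.83 ± 0.13), IAA2 (-0.63 ± 0.11) and GH3.5 (-1.17 ± 0.20) (edgeR adjusted p of at most 7.47e-04). The type-A response regulator ARR7, which cytokinin induces, rose (log2 fold change 0.93 ± 0.15, edgeR adjusted p = 4.63e-04). The light-harvesting genes LHCB2.1 (-1.68 ± 0.10), LHCB1.1 (-1.67 ± 0.19) and LHCA1 (-0.73 ± 0.11) fell, as did the touch gene TCH4 (-2.53 ± 0.34), with edgeR adjusted p of at most 2.16e-04. In the same photosynthetic list GAPA rose (log2 fold change 0.52 ± 0.13, edgeR adjusted p = 0.0140), with adjusted p = 0.137 with only the groups compared and 0.169 without microRNA-line replicate 1. The other risers were RBCS3B (0.43 ± 0.13) and RCA (0.38 ± 0.12), named after their values were seen.

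The other lists did not pass camera, whose adjusted p was at least 0.0677. They were KNOX class I (1 of 4 fell, alone 2 fell), BELL and KNOX class II (2 of 8 rose and 1 fell), meristem maintenance (1 of 12 rose and 1 fell, alone 2 rose and 1 fell), TCP (1 of 10 rose and 2 fell, alone 2 rose and 2 fell), cytokinin turnover (2 of 14 rose and 4 fell, alone 2 rose and 5 fell), type-A response regulator (3 of 8 rose), gibberellin (2 of 9 fell), auxin response (4 of 13 fell, alone 5 fell), auxin transport (1 of 12 rose), lignin (1 of 15 rose), touch and stress (3 of 13 fell, alone 1 rose and 4 fell), jasmonate (3 of 11 fell, alone 5 fell) and photosynthetic (3 of 8 rose and 4 fell). The organ boundary list had 0 of 12 in edgeR, 0 in DESeq2 and in limma-voom, 1 at an unadjusted p under 0.05, and the stem, xylem and phloem list had 0 of 9 in edgeR, 1 lower in DESeq2, 0 in limma-voom, 2 at an unadjusted p under 0.05. The organ boundary and TCP lists had a median, a mean and a camera direction of differing sign. Between tools, list counts moved by over 1.5 times for KNOX class I (2 fallers in DESeq2), BELL and KNOX class II (0 fallers in limma-voom), lignin (2 risers in DESeq2 and limma-voom), jasmonate (0 fallers in limma-voom) and circadian clock (2 risers in DESeq2 and limma-voom). Genes that rose and fell numbered 455 and 1558 without microRNA replicate 1, 318 and 1332 without replicate 2, and 344 and 1603 with only these groups in the fit. Without microRNA replicate 2 the lateral organ list had 3 risers and the carpel list 3 fallers, and the falling floral meristem members dropped to 1 without it, microRNA replicate 1 or ap1-1 replicate 3.

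DEX-sprayed 35S::STM-GR plants were compared with mock-sprayed ones to ask which genes respond within 5 h of moving STM into the nucleus. STM counts, which include the transgene, were 822 ± 47.6 CPM with DEX (n = 3) and 814 ± 8.22 CPM with mock (n = 3), against 46.8 ± 0.884 CPM in wild type (n = 2). KNAT2 rose to 30.0 ± 2.35 CPM (n = 3) against 12.8 ± 1.18 CPM (n = 3), with log2 fold change 1.23 ± 0.10, edgeR adjusted p = 3.12e-06. KNAT1 rose to 64.9 ± 6.66 CPM (n = 3) against 40.8 ± 3.02 CPM (n = 3), with log2 fold change 0.67 ± 0.13, edgeR adjusted p = 0.00284. KNAT6 was not called (0.13 ± 0.10). The genes that give flower meristems their identity rose as well, AP1 (0.66 ± 0.06), LFY (0.61 ± 0.13) and UFO (1.40 ± 0.22), with edgeR adjusted p of at most 0.00707. In all, 1207 genes rose and 1553 fell, and 207 of the first and 188 of the second changed at least 2-fold.

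**Figure D1:**
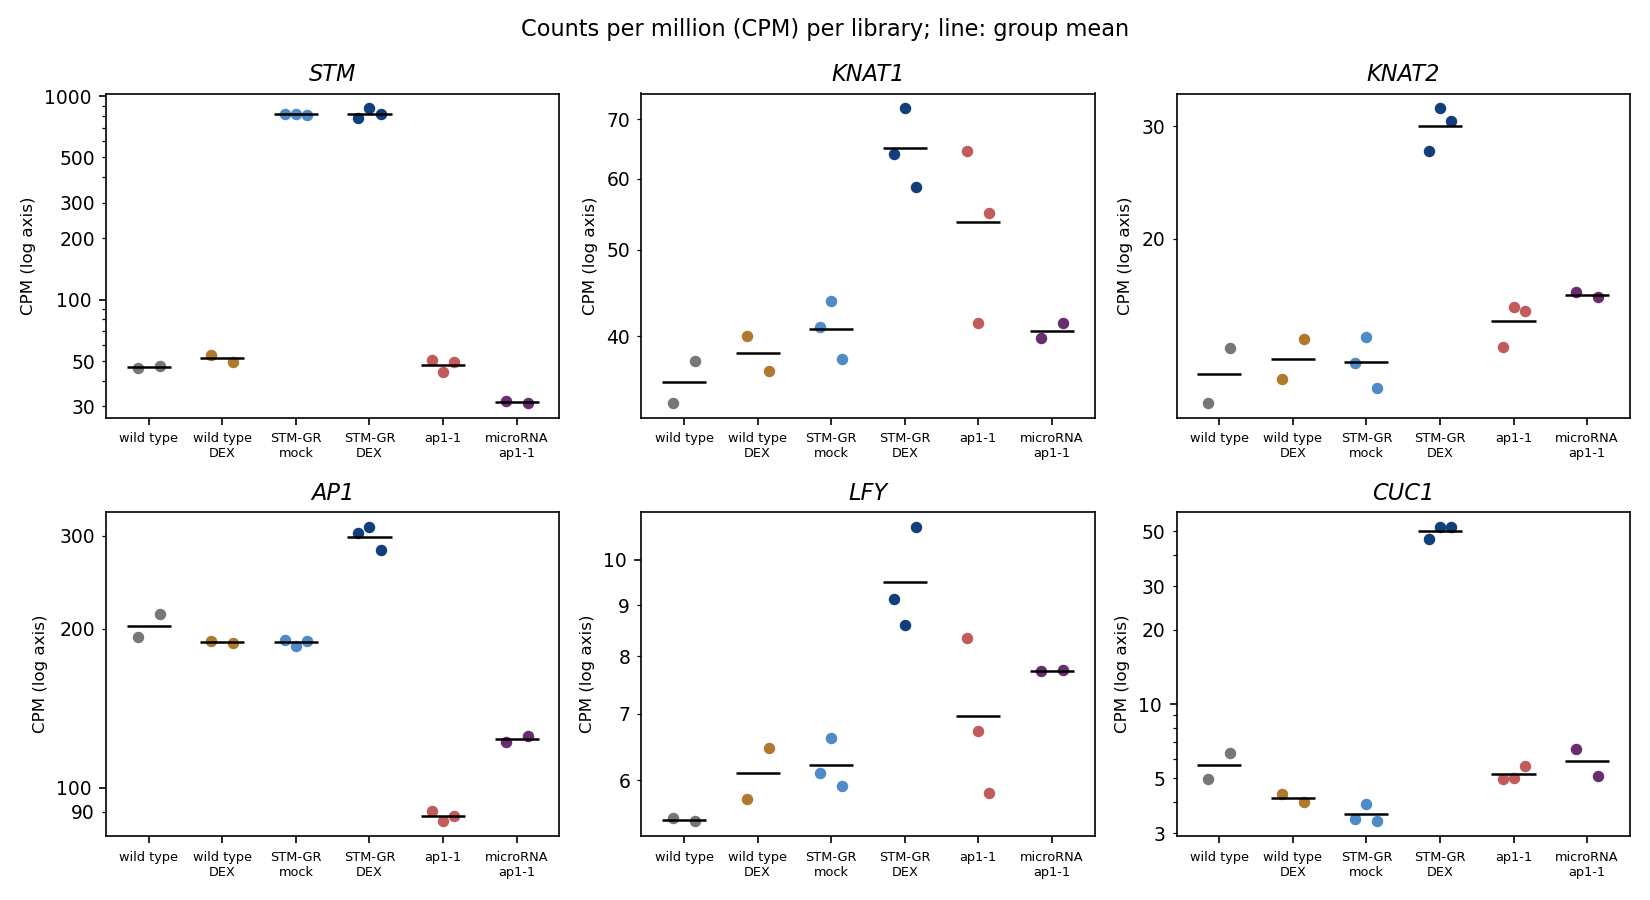
CPM of 6 genes in each library on log axes, with the group mean as a line. CUC1, KNAT2 and AP1 were highest in DEX-sprayed 35S::STM-GR, where CUC1 averaged 50.1 CPM, and STM was lowest in the microRNA line, at 31.5 CPM.

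The strongest rises were those of the transporter gene OCT6 (AT1G16370), the boundary gene CUC1 (AT3G15170) and BGLU45 (AT1G61810), SHB1 (AT4G25350), TPS04 (AT1G61120) and SRG1 (AT1G17020). Their log2 fold changes were 5.62 ± 0.24, 3.81 ± 0.12, 3.21 ± 0.22, 3.05 ± 0.18, 2.96 ± 0.32 and 2.65 ± 0.26, in that order (edgeR adjusted p of at most 3.14e-05). CUC1, which separates organs and meristems, went from 3.57 ± 0.322 to 50.1 ± 3.31 CPM. The strongest falls were those of FTM1 (-2.62 ± 0.49), ARD3 (-2.35 ± 0.43), MYB82 (-2.04 ± 0.24), CSLA01 (-1.81 ± 0.20) and BSMT1 (-1.80 ± 0.18) (edgeR adjusted p of at most 0.00262). ARD3 also fell in DEX-sprayed against unsprayed wild type, as given below. DFR fell by 2.28 ± 0.62 on the log2 scale (edgeR adjusted p = 0.0252), but the adjusted p was 0.0521 with only the groups compared, 0.0837 without STM-GR DEX replicate 1, 0.0669 without STM-GR DEX replicate 2, 0.0739 without STM-GR DEX replicate 3 and 0.0852 without STM-GR mock replicate 2.

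In the KNOX class I list 2 of 4 rose (the same number adjusted over the list alone). This list had camera adjusted p = 0.0241, and adjusted p = 0.339 with an estimated correlation. Meristem and boundary genes rose singly, AIL7 (2.16 ± 0.19), AIL6 (0.86 ± 0.10), CLV1 (0.53 ± 0.09), LSH3 (0.91 ± 0.15), BOP2 (2.35 ± 0.09) and BOP1 (0.95 ± 0.15) (edgeR adjusted p of at most 0.00148). AIL6 and AIL7 are AINTEGUMENTA-like genes of meristems, and BOP1 and BOP2 act at organ bases. The BELL partner PNF, of a family that binds KNOX proteins, and KNAT4 rose, and BEL1 fell: PNF (0.61 ± 0.13), KNAT4 (0.70 ± 0.08) and BEL1 (-0.45 ± 0.09). The polarity genes KAN1, AS1 and REV rose and ATHB8 fell, KAN1 (1.53 ± 0.12), AS1 (0.64 ± 0.07), REV (0.52 ± 0.07) and ATHB8 (-0.56 ± 0.07). The senescence factor NAP (1.36 ± 0.24) rose and the carpel gene HEC2 (-1.36 ± 0.28) fell.

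Cytokinin genes were among those that fell. Of the type-A response regulators, induced by cytokinin, 4 of 8 fell (5 fell adjusted over the list alone). Its camera adjusted p was 0.00372, and adjusted p = 0.279 with an estimated correlation. These were ARR6 (-1.21 ± 0.12), ARR5 (-1.07 ± 0.20), ARR7 (-0.75 ± 0.14) and ARR4 (-0.70 ± 0.11). In cytokinin synthesis and turnover 3 of 14 fell (the same number adjusted over the list alone). The camera test gave adjusted p = 0.0414, and adjusted p = 0.238 with an estimated correlation. The cytokinin oxidases CKX3 (-1.31 ± 0.12) and CKX5 (-0.85 ± 0.08), which break the hormone down, were among them. For auxin transport 5 of 12 fell (6 fell adjusted over the list alone). As a list it had camera adjusted p = 0.0241, and adjusted p = 0.238 with an estimated correlation. The carrier genes LAX2 (-0.84 ± 0.08) and PIN4 (-0.53 ± 0.10) were among them. Of gibberellin genes, GA20OX1 (-1.11 ± 0.21), GA2OX1 (-1.38 ± 0.14) and GA2OX2 (-0.41 ± 0.09) fell and GA2OX4 (1.24 ± 0.24) rose. GA2OX2 also fell in DEX-sprayed against unsprayed wild type, as given below.

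In the jasmonate list 5 of 11 fell (6 fell adjusted over the list alone). In camera the adjusted p was 0.00622, and adjusted p = 0.365 with an estimated correlation. JAZ10, a gene for a jasmonate repressor, was 1 of them, at 24.7 ± 3.58 CPM (n = 3) against 49.4 ± 3.65 CPM (n = 3) (edgeR adjusted p = 1.24e-04). Of the clock genes 5 of 11 rose (8 rose adjusted over the list alone), including PRR9 (1.00 ± 0.19), CCA1 (0.68 ± 0.12), FKF1 (0.51 ± 0.07) and PRR5 (0.49 ± 0.07). Camera gave adjusted p = 2.37e-05, and adjusted p = 0.0871 with an estimated correlation. FKF1 and PRR5 were also higher in DEX-sprayed wild type than in mock-sprayed STM-GR plants. FKF1 was at 61.9 against 40.4 CPM (log2 difference 0.61 ± 0.08) and PRR5 at 87.6 against 60.0 CPM (0.55 ± 0.08). The rise of these genes over mock was thus not shown to need STM-GR. In the test of differing DEX responses 0 of 11 clock genes were called, although camera had the list higher, as given below. In the touch and stress list 2 of 13 rose (the same number adjusted over the list alone). This list had camera adjusted p = 0.0273, and adjusted p = 0.576 with an estimated correlation. The called members were the cold-response genes CBF2 (1.85 ± 0.31) and CBF3 (1.06 ± 0.29). CBF3 lost the call without STM-GR DEX replicate 2 or 3 or any mock replicate, with edgeR adjusted p of 0.0592 to 0.107. In the cell cycle list 1 of 11 fell (the same number adjusted over the list alone), the cyclin gene CYCD3;1 (log2 fold change -0.30 ± 0.06, edgeR adjusted p = 0.00344). Its camera adjusted p was 0.0414, and adjusted p = 0.576 with an estimated correlation. In lignin synthesis F5H (0.99 ± 0.14) rose and COMT1 (-0.63 ± 0.12) fell.

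The remaining lists had camera adjusted p of at least 0.153. They were BELL and KNOX class II (3 of 8 rose and 1 fell, alone 4 rose and 1 fell), floral meristem identity and flowering (6 of 18 rose and 2 fell, alone 6 rose and 3 fell), floral organ identity (1 of 14 rose and 1 fell, alone 2 rose and 4 fell), organ boundary (2 of 12 rose and 1 fell), meristem maintenance (4 of 12 rose, alone 4 rose and 1 fell), lateral organ and polarity (4 of 17 rose and 5 fell, alone 5 rose and 7 fell), TCP (1 of 10 fell), gibberellin (1 of 9 rose and 4 fell), auxin response (1 of 13 rose and 1 fell, alone 1 rose and 3 fell), lignin (1 of 15 rose and 1 fell), carpel and ovule (2 of 9 fell, alone 3 fell) and photosynthetic (1 of 8 fell, alone 1 rose and 1 fell). The stem, xylem and phloem list had 0 of 9 in edgeR, 1 lower in DESeq2, 0 in limma-voom, 2 at an unadjusted p under 0.05, and the mature pollen list had 0 of 3 in edgeR, 0 in DESeq2 and in limma-voom, 1 at an unadjusted p under 0.05. For tapetum and pollen wall there were 0 of 15 in edgeR, 0 in DESeq2 and in limma-voom, 0 at an unadjusted p under 0.05. Median, mean and camera direction differed in sign for floral organ identity, meristem maintenance, lateral organ and photosynthetic genes. Between tools, list counts moved by over 1.5 times for floral organ identity (3 fallers in DESeq2, 2 fallers in limma-voom), organ boundary (0 fallers in DESeq2 and limma-voom), meristem maintenance (1 faller in DESeq2), auxin response (2 fallers in DESeq2) and photosynthetic (1 riser in DESeq2). Genes that rose and fell numbered 710 and 998 without STM-GR DEX replicate 2, 760 and 942 without DEX replicate 3, 657 and 809 without mock replicate 1, 675 and 877 without mock replicate 3, and 2262 and 2792 with only the 6 STM-GR libraries in the fit. Falling jasmonate members numbered 1 without STM-GR mock replicate 3, 2 without STM-GR DEX replicate 1 or 2 or STM-GR mock replicate 1, 3 without STM-GR DEX replicate 3, and falling auxin transport members 3 without STM-GR DEX replicate 1 or STM-GR mock replicate 1 or 3.

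**Figure D2:**
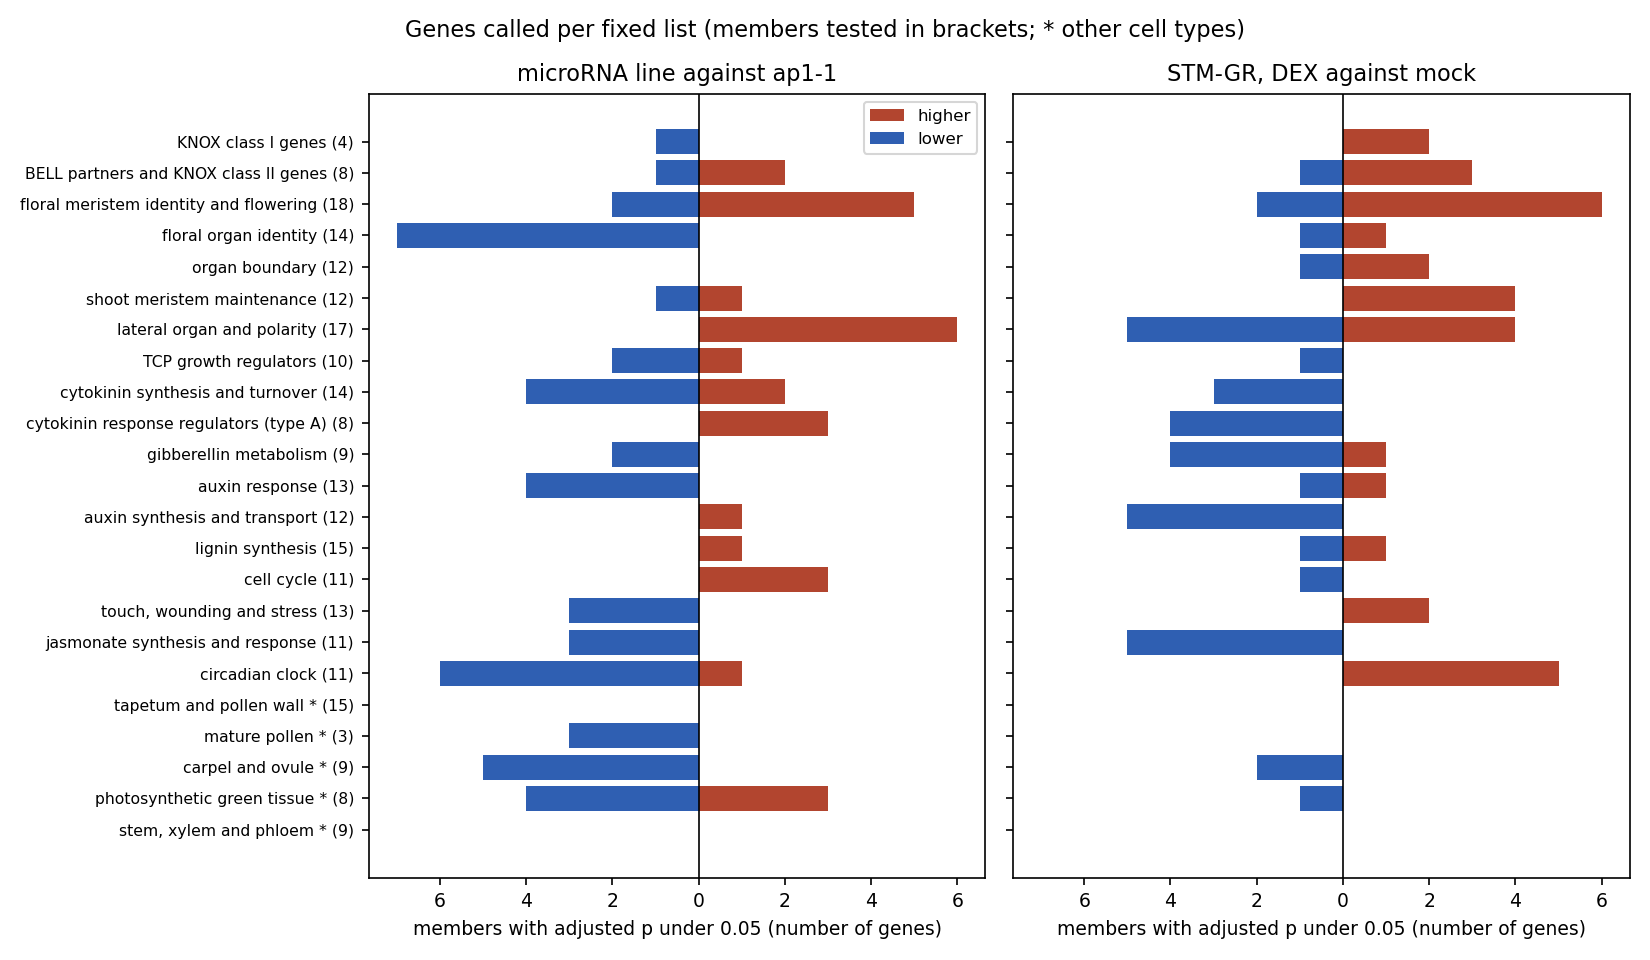
Number of members called higher or lower in each of the 23 fixed gene lists, for the microRNA line against ap1-1 and for DEX against mock in 35S::STM-GR. Of the type-A response regulators 3 rose in the first and 4 fell in the second, and of the clock genes 6 fell in the first and 5 rose in the second.

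Opposite responses to STM induction and STM/BP silencing were then counted, in comparisons that share no library. Of the genes that rose on induction 231 fell on silencing, where independent calls would give 138, and 172 fell on induction and rose on silencing, against 75.6. Both exceeded independence in Fisher's exact test, one-sided (adjusted p = 8.42e-16 and 1.48e-24). This test counts genes as independent draws, which genes that vary together are not, so its p-values overstate the evidence. The number that rose in both was 84 against 58.7 (exact adjusted p = 7.92e-04), and 145 fell in both against 177 (exact adjusted p = 0.997). Without ap1-1 replicate 3, 107 rose in both against 94.3, an excess that did not pass (unadjusted exact p = 0.092). In log2 fold changes for induction and silencing, the clock genes CCA1 (0.68 and -1.88) and PRR9 (1.00 and -2.32) and the reverse pair ARR7 (-0.75 and 0.93) and ATHB8 (-0.56 and 0.54) moved in opposite ways. CCA1, PRR9 and ARR7 were not called in the test of differing DEX responses, so their induction responses were not shown to need STM-GR. ARR7 was called there with only the groups compared (-0.74 ± 0.14, edgeR adjusted p = 0.0153). The labels state no harvest date, so differences in harvest were not separated from silencing for clock genes. AP1 (0.66 and 0.49), BOP2 (2.35 and 0.65) and AS1 (0.64 and 0.50) rose in both and GA2OX1 (-1.38 and -1.59) and GA2OX2 (-0.41 and -1.01) fell in both. The clock gene FKF1 (0.51 and 0.47) and the CCA1 relative RVE2 (0.95 and 2.89) also rose in both. FKF1 was higher in DEX-sprayed wild type than in mock-sprayed STM-GR plants too, as given above. GA2OX2 fell on DEX in wild type too, without STM-GR, as given below. Across all genes tested, Spearman's rho was -0.14 and Pearson's r -0.06; genes are not independent replicates.

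Of genes that rose on induction and fell on silencing there were 132 without microRNA-line replicate 1, 120 without microRNA-line replicate 2, 139 without STM-GR DEX replicate 2, 151 without STM-GR DEX replicate 3, 124 without STM-GR mock replicate 1 and 139 without STM-GR mock replicate 3. Of genes that fell on induction and rose on silencing there were 288 without ap1-1 replicate 3, 85 without microRNA-line replicate 1, 66 without microRNA-line replicate 2, 105 without STM-GR DEX replicate 2, 106 without STM-GR DEX replicate 3, 99 without STM-GR mock replicate 1 and 108 without STM-GR mock replicate 3. With a change of at least 2-fold in both comparisons there were 16 and 10 against 12.7 and 1.02, with an unadjusted exact p = 0.203 and 8.08e-08. The 10 that fell on induction and rose on silencing included ARD3, which also fell on DEX in wild type. At 2-fold, 18 genes fell in both against 11.5 for independent calls, and 3 rose in both against 1.12.

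**Figure D3:**
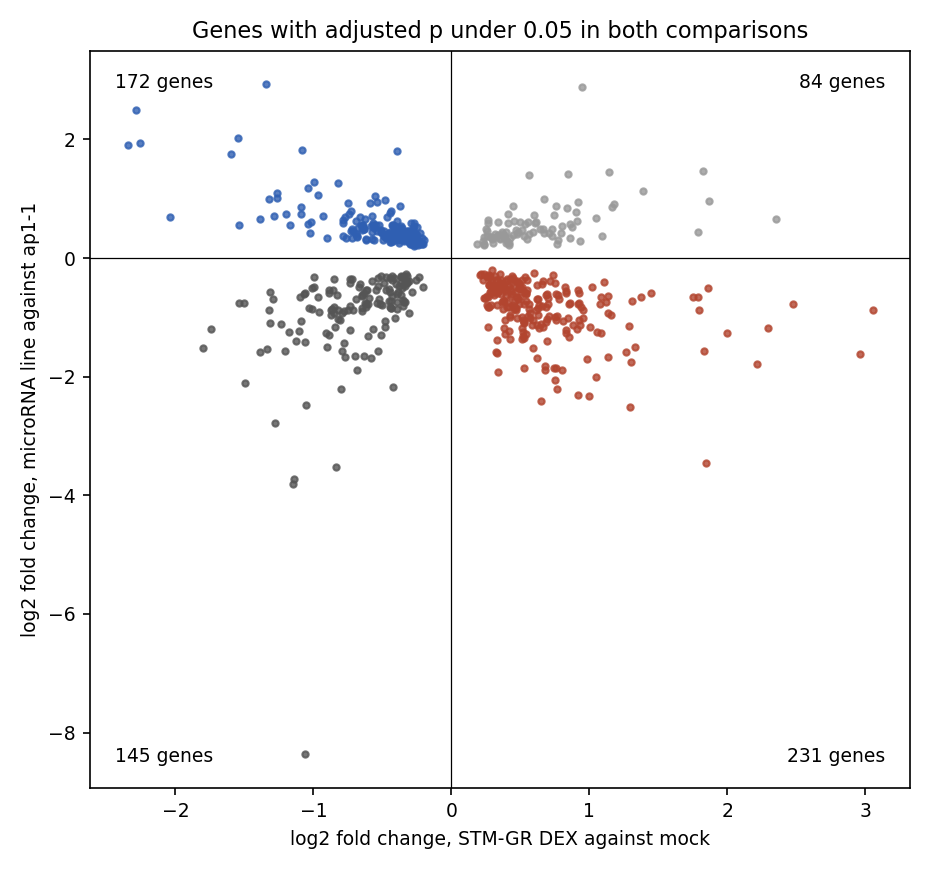
Log2 fold change on induction against log2 fold change on silencing for genes called in both comparisons, 1 point per gene. The quadrants hold 231 genes that rose on induction and fell on silencing, 172 that did the reverse, 84 that rose in both and 145 that fell in both.

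DEX-sprayed wild type was compared with unsprayed wild type to find responses that need no STM-GR. HSP23.6-MITO, a mitochondrial heat shock protein gene, had 0 counts in unsprayed plants and was at least 68.8-fold higher over a floor of 3 counts for the group. The phosphate carrier gene PHT3;2 was 278-fold (95% counting interval 76.6 to 2301) higher and the kinase gene AGC2-1 58.1-fold (95% counting interval 19.5 to 284). GSTU9, a glutathione transferase gene, rose from 0.103 ± 0.0879 to 6.41 ± 1.71 CPM (n = 2 each, edgeR adjusted p = 1.09e-04). AOX1D, for an alternative oxidase, was 224-fold (95% counting interval 39.8 to 8889) higher, and its edgeR adjusted p went from 0.00393 to 0.0893 without wild-type replicate 2. GSTF7 rose (log2 fold change 5.69 ± 0.96, edgeR adjusted p = 0.0104), but its adjusted p was 0.0565 without wild-type replicate 1, 0.168 without wild-type replicate 2 and 0.0862 without wild-type DEX replicate 2. In all, 105 genes rose and 29 fell, with 86 and 7 changing at least 2-fold.

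None of STM, KNAT1, KNAT2, KNAT6, AP1, LFY and UFO was called, with log2 fold changes from -0.10 to 0.25 and edgeR adjusted p above 0.05. The strongest falls, ARD3 (-1.52 ± 0.30), TIR (-1.03 ± 0.16), LOX3 (-0.93 ± 0.17), EXPA16 (-0.90 ± 0.18), HTA6 (-0.82 ± 0.17) and HTB2 (-0.81 ± 0.13), all lost the call without wild-type replicate 2 or wild-type DEX replicate 2. Their adjusted p was then 0.0512 to 0.609. HTA6 and HTB2 encode histones. In the fixed lists the called genes were LOX3, the heat shock factor HSFA2 (log2 fold change 2.18 ± 0.31, edgeR adjusted p = 0.00271) and GA2OX2 (log2 fold change -0.54 ± 0.11, edgeR adjusted p = 0.0398). HSFA2 had an adjusted p of 0.0857 with only the groups compared and 0.0537 without wild-type DEX replicate 2. In its touch and stress list 1 of 13 rose (1 rose and 2 fell adjusted over the list alone), with a median log2 fold change of -0.17 and 2 fallers in DESeq2. The camera test gave adjusted p = 0.994, and adjusted p = 0.996 with an estimated correlation. For GA2OX2 the adjusted p without any 1 of the 4 libraries was 0.0766 to 0.320.

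The cell cycle list was lower in camera. Its called members were 0 of 11 in edgeR, 0 in DESeq2 and in limma-voom, 5 at an unadjusted p under 0.05, and 4 fell adjusted over the list alone. As a list it had camera adjusted p = 6.32e-04, and adjusted p = 0.996 with an estimated correlation. The lowest adjusted p were those of KN (-0.31 ± 0.09), CYCA1;1 (-0.38 ± 0.12), AUR1 (-0.28 ± 0.09) and CDKB1;1 (-0.45 ± 0.16). The photosynthetic list was lower too, with 0 of 8 in edgeR, 0 in DESeq2 and in limma-voom, 0 at an unadjusted p under 0.05, and 0 changed adjusted over the list alone. In camera the adjusted p was 0.0407, and adjusted p = 0.996 with an estimated correlation. Genes that rose and fell numbered 158 and 104 without wild-type replicate 1, 39 and 4 without replicate 2, and 38 and 1 without wild-type DEX replicate 2. Falling genes numbered 12 without DEX replicate 1, DESeq2 gave 166 and 80, and the fit with only these groups 60 and 6.

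**Figure D4:**
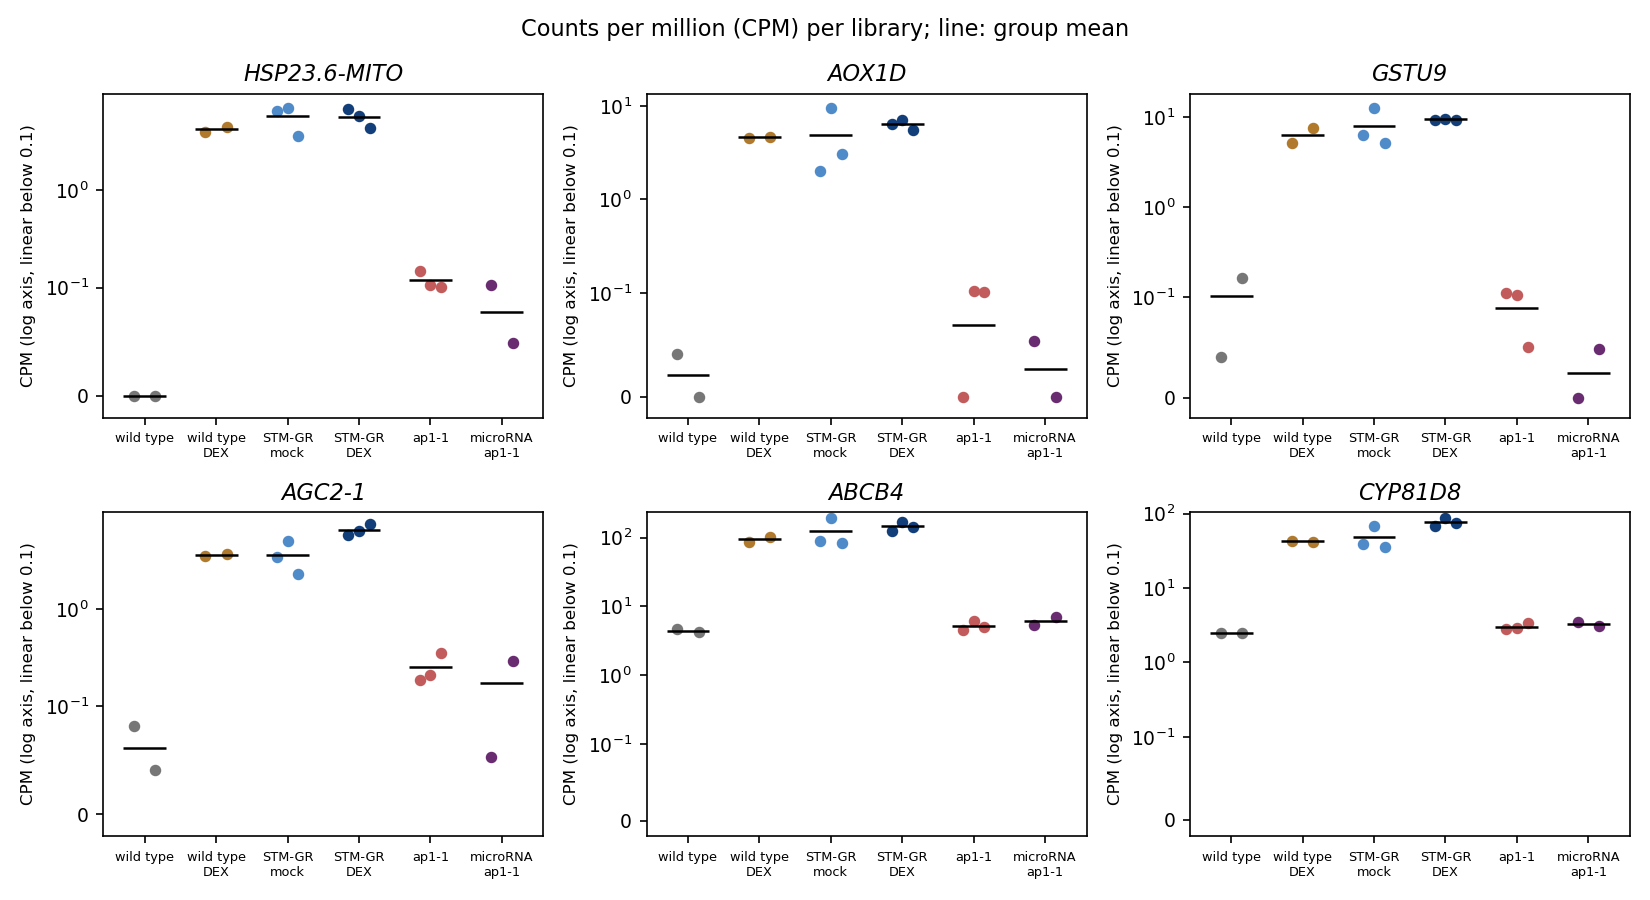
CPM of 6 genes in each library, on axes that are logarithmic above 0.1 CPM and linear below, with the group mean as a line; ABCB4 and CYP81D8 were chosen after their values were seen. GSTU9 averaged 6.41 CPM in DEX-sprayed wild type and 8.09 CPM in mock-sprayed 35S::STM-GR, against 0.103 CPM in unsprayed wild type.

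The DEX responses of 35S::STM-GR and wild type shared 25 genes that rose in both, against 5.84 for independent calls, and 13 that fell in both, against 2.07. Fisher's exact test, one-sided, gave adjusted p = 1.76e-09 and 5.59e-08, again with genes counted as independent draws. In opposite directions, 2 rose in 35S::STM-GR and fell in wild type and 1 fell and rose. Genes rising in both numbered 11 without STM-GR DEX replicate 2, 14 without STM-GR DEX replicate 3, 10 without STM-GR mock replicate 1, 75 without STM-GR mock replicate 2, 9 without STM-GR mock replicate 3, 3 without wild-type DEX replicate 2, 43 without wild-type replicate 1 and 6 without wild-type replicate 2. Genes falling in both numbered 8 without STM-GR DEX replicate 1, 4 without STM-GR DEX replicate 2, 5 without STM-GR DEX replicate 3, 1 without STM-GR mock replicate 1, 21 without STM-GR mock replicate 2, 3 without STM-GR mock replicate 3, 6 without wild-type DEX replicate 1, 0 without wild-type DEX replicate 2, 20 without wild-type replicate 1 and 1 without wild-type replicate 2, all in edgeR, and 38 in DESeq2 with all libraries. Spearman's rho across genes was 0.38 and Pearson's r 0.21. At an adjusted p of 0.01, 4 genes rose in both against 1.62 for independent calls (unadjusted exact p = 0.079). At that threshold 0 fell in both against 0.29, so neither overlap passed the test there.

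Whether DEX acted differently with and without STM-GR was tested as the difference between the responses of 35S::STM-GR, against mock spray, and wild type, against no spray. CUC1 differed by 4.25 ± 0.20 on the log2 scale (edgeR adjusted p = 4.58e-08), KNAT2 by 1.14 ± 0.17 (edgeR adjusted p = 0.00175) and AP1 by 0.77 ± 0.10 (edgeR adjusted p = 5.68e-04), each higher with STM-GR. Larger responses with STM-GR were also found for OCT6 (6.54 ± 0.70), SHB1 (3.44 ± 0.30), BGLU45 (2.75 ± 0.36), SRG1 (2.57 ± 0.45), BOP2 (2.25 ± 0.15), AIL7 (1.85 ± 0.31), AIL6 (0.98 ± 0.17), KAN1 (1.51 ± 0.19), AS1 (0.79 ± 0.10) and KNAT4 (0.72 ± 0.13) (edgeR adjusted p of at most 0.00646). Lower responses were found for GA2OX1 (-1.45 ± 0.21) and CKX5 (-0.70 ± 0.12) (edgeR adjusted p of at most 0.00631). KNAT1 (log2 fold change 0.57 ± 0.20, edgeR adjusted p = 0.238), LFY (log2 fold change 0.45 ± 0.21, edgeR adjusted p = 0.479) and UFO (log2 fold change 1.16 ± 0.37, edgeR adjusted p = 0.161) were not called, so their responses were not shown to differ. With only the groups compared in the fit KNAT1 was called (0.57 ± 0.13, edgeR adjusted p = 0.0476). In all, 205 genes had a higher and 214 a lower response with STM-GR. Because the wild-type reference was unsprayed, a gene raised by spray alone also counts as a lower response, and one lowered by it as a higher one.

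Of the type-A response regulators 1 of 8 was lower with STM-GR (5 lower adjusted over the list alone), and that was ARR6 (log2 fold change -0.87 ± 0.19, edgeR adjusted p = 0.0259). Camera gave adjusted p = 0.00131, and adjusted p = 0.179 with an estimated correlation. In cytokinin turnover 2 of 14 were lower (the same number adjusted over the list alone). This list had camera adjusted p = 0.0384, and adjusted p = 0.179 with an estimated correlation. In auxin transport 2 of 12 were lower (1 higher and 4 lower adjusted over the list alone). Its camera adjusted p was 0.0384, and adjusted p = 0.179 with an estimated correlation. In the jasmonate list 1 of 11 was lower (1 higher and 2 lower adjusted over the list alone). The camera test gave adjusted p = 0.0384, and adjusted p = 0.635 with an estimated correlation. The clock list was higher in camera, with 0 of 11 in edgeR, 0 in DESeq2 and in limma-voom, 1 at an unadjusted p under 0.05, and 1 higher adjusted over the list alone. As a list it had camera adjusted p = 0.00357, and adjusted p = 0.179 with an estimated correlation. The touch and stress list was higher in camera, although HSFA2 was lower (1 of 13 was lower, 4 higher and 1 lower adjusted over the list alone). In camera the adjusted p was 0.0384, and adjusted p = 0.744 with an estimated correlation.

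Higher and lower responses numbered 95 and 104 without wild-type DEX replicate 1, 120 and 100 without DEX replicate 2, and 122 and 130 without wild-type replicate 2. Higher responses numbered 134 without STM-GR DEX replicate 2, and lower ones 136 and 139 without mock replicates 1 and 3 and 340 in DESeq2. Between tools, list counts moved by over 1.5 times for type-A response regulators (3 lower in DESeq2), jasmonate (1 higher in DESeq2) and touch and stress (3 higher in DESeq2, 0 lower in limma-voom). Members with a lower response numbered 1 without wild-type DEX replicate 2 (cytokinin turnover), 0 without wild-type DEX replicate 1, 1 without STM-GR DEX replicate 2 or 3 or STM-GR mock replicate 1 or 3 or wild-type DEX replicate 2 (auxin transport) and 0 without wild-type DEX replicate 2 or wild-type replicate 2, 2 without wild-type replicate 1 (jasmonate). The call of ARR6 ended without STM-GR DEX replicate 2 or 3, mock replicate 2 or 3, wild-type DEX replicate 1 or wild-type replicate 2 (edgeR adjusted p of 0.0550 to 0.165). That of HSFA2 ended without any DEX-sprayed STM-GR replicate, mock replicate 1 or 2, wild-type DEX replicate 2 or wild-type replicate 1 (0.0550 to 0.172).

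The mutant ap1-1 was compared with wild type to describe the background of the microRNA line. AP1 (AT1G69120), the mutated floral identity gene, fell to 88.3 ± 1.90 CPM (n = 3) against 203 ± 14.3 CPM (n = 2), with log2 fold change -1.20 ± 0.07, edgeR adjusted p = 2.21e-07. Flowering genes of the inflorescence rose: SOC1 (1.11 ± 0.09), FD (1.60 ± 0.17), FUL (0.92 ± 0.10), AGL71 (2.37 ± 0.22) and AGL72 (2.41 ± 0.33) (edgeR adjusted p of at most 4.07e-04). AGL71 and AGL72 are similar neighbours that can share reads. The branching repressor BRC1 (2.36 ± 0.24), TCP1 (1.46 ± 0.16) and the floral organ gene SEP4 (1.02 ± 0.15) rose, with edgeR adjusted p of at most 7.95e-04. STM (0.03 ± 0.08), KNAT2, LFY and UFO were not called (0.27, 0.36 and -0.68). LFY was called without ap1-1 replicate 3 (0.47 ± 0.15, edgeR adjusted p = 0.0452). KNAT1 rose (log2 fold change 0.60 ± 0.14, edgeR adjusted p = 0.0176), but its adjusted p was 0.189 with only the groups compared, 0.155 without wild-type replicate 1 and 0.0525 without wild-type replicate 2. In all, 1178 genes rose and 1128 fell, with 261 and 257 changing at least 2-fold.

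The strongest rises also included FMO GS-OX2 (2.94 ± 0.21), HBI1 (2.46 ± 0.16) and 2A6 (2.43 ± 0.26), and the strongest falls MLP168 (-3.44 ± 0.48), AAE11 (-3.35 ± 0.55), NRPD1B (-3.03 ± 0.18), EXPA11 (-2.81 ± 0.32) and DML1 (-2.71 ± 0.10), with edgeR adjusted p of at most 0.00200. SWEET9, a nectary sugar transporter gene, fell (log2 fold change -4.16 ± 0.94, edgeR adjusted p = 0.0136), with adjusted p = 0.0683 with only the groups compared and 0.220 without wild-type replicate 1. NRPD1B was at 14.0 ± 4.56 CPM (n = 3) against 113 ± 5.31 CPM (n = 2), and in the microRNA line at 131 ± 18.0 CPM. DML1 was at 25.8 ± 3.79 against 168 ± 4.44 CPM, and in the microRNA line at 146 ± 12.4 CPM. The cytokinin oxidase CKX3, GA2OX2 and the jasmonate genes OPR3 and JAZ10 fell, CKX3 (-1.16 ± 0.13), GA2OX2 (-0.75 ± 0.10), OPR3 (-0.64 ± 0.09) and JAZ10 (-0.96 ± 0.14) (edgeR adjusted p of at most 6.22e-04).

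**Figure D5:**
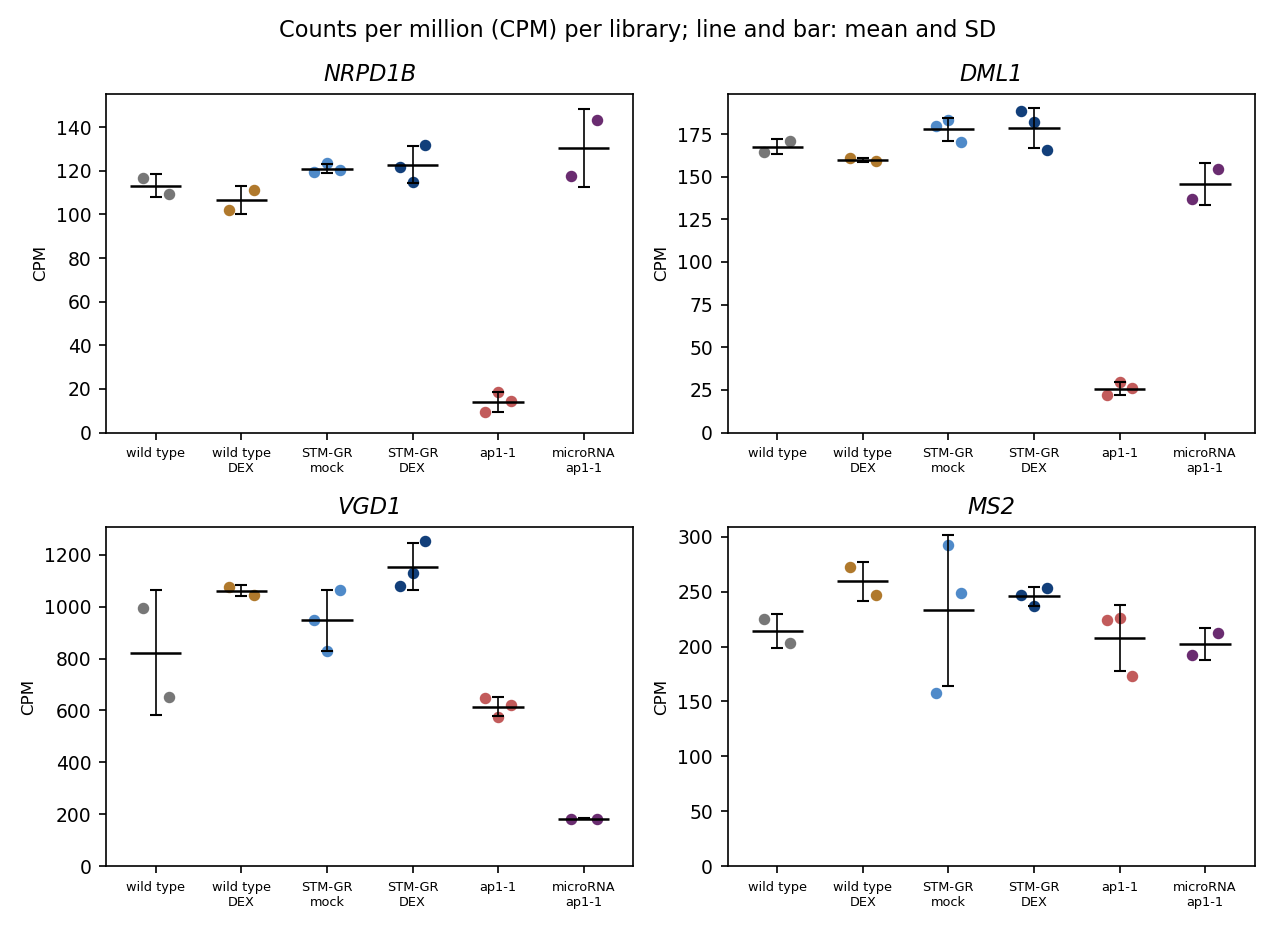
CPM of NRPD1B, DML1, VGD1 and MS2 in each library, with the group mean as a line and 1 SD as error bars. NRPD1B averaged 14.0 CPM in ap1-1 against 113 in wild type and 131 in the microRNA line.

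Lists of meristem and young organ genes were higher in ap1-1 in camera. They were floral meristem identity and flowering (7 of 18 rose and 1 fell, 9 rose and 2 fell alone, camera adjusted p = 0.00561), KNOX class I (2 of 4 rose, the same number alone, camera adjusted p = 0.0497), organ boundary (5 of 12 rose, 6 rose alone, camera adjusted p = 0.0108), meristem maintenance (3 of 12 rose, 5 rose and 1 fell alone, camera adjusted p = 0.0427), lateral organ and polarity (2 of 17 rose, 5 rose alone, camera adjusted p = 0.00108), TCP (4 of 10 rose, 5 rose alone, camera adjusted p = 0.00161) and cell cycle (5 of 11 rose, 8 rose alone, camera adjusted p = 2.09e-04), where alone stands for adjusted over the list alone. Each had adjusted p = 0.334 with an estimated correlation. In the jasmonate list 5 of 11 fell (8 fell adjusted over the list alone). Camera gave adjusted p = 2.09e-04, and adjusted p = 0.334 with an estimated correlation. In lignin synthesis 4 of 15 fell (6 fell adjusted over the list alone). This list had camera adjusted p = 0.0333, and adjusted p = 0.559 with an estimated correlation.

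Counts rising and falling in ap1-1 were 94 and 140 with only these groups in the fit, 1855 and 1775 without ap1-1 replicate 3 and 392 and 599 without wild-type replicate 1, and 587 rose without wild-type replicate 2. List members that rose numbered 4 without wild-type replicate 1 (floral meristem identity and flowering), 0 without wild-type replicate 1 or 2, 1 without ap1-1 replicate 1 or 2 or 3 (KNOX class I), 1 without wild-type replicate 1, 2 without ap1-1 replicate 1 or wild-type replicate 2 (organ boundary), 1 without wild-type replicate 1 (meristem maintenance), 1 without wild-type replicate 1, 5 without ap1-1 replicate 3 (lateral organ and polarity), 2 without wild-type replicate 1 (TCP) and 2 without wild-type replicate 1, 3 without wild-type replicate 2 (cell cycle). Between tools, list counts moved by over 1.5 times for KNOX class I (1 riser in limma-voom), meristem maintenance (1 faller in DESeq2) and lateral organ and polarity (4 risers in DESeq2). Lignin members that fell numbered 1 without wild-type replicate 2.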

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

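The tests of dexamethasone itself and of shared spray or handling were chosen only after the result was seen. The test of the difference between the 2 DEX responses called 419 genes. Higher responses in 35S::STM-GR included the log2 differences of OCT6 (6.54 ± 0.70), CUC1 (4.25 ± 0.20), SHB1 (3.44 ± 0.30), BGLU45 (2.75 ± 0.36), NTM1 (2.64 ± 0.44), SRG1 (2.57 ± 0.45), KNAT2 (1.14 ± 0.17) and AP1 (0.77 ± 0.10). TIR was also called higher, 1.05 ± 0.21, with a log2 fold change of 0.02 on DEX in 35S::STM-GR and -1.03 in wild type. Lower responses included CSLA01 (-1.76 ± 0.30), MYB82 (-1.81 ± 0.34) and BSMT1 (-1.86 ± 0.27). The others were GSTF7 (-4.77 ± 1.14), AGC2-1 (-4.87 ± 0.68), GSTU9 (-5.66 ± 0.68), AOX1D (-7.07 ± 1.29), PHT3;2 (-7.17 ± 0.94) and HSP23.6-MITO (-9.64 ± 0.92), whose levels in unsprayed wild type were near 0, so these fitted differences are no bounds.

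In CPM in unsprayed wild type, DEX-sprayed wild type, mock-sprayed and DEX-sprayed 35S::STM-GR, the last 6 genes were GSTF7 (0.103, 5.58, 5.97 and 11.1), AGC2-1 (0.0616, 3.58, 3.58 and 6.49), GSTU9 (0.103, 6.41, 8.09 and 9.49), AOX1D (0.0205, 4.61, 4.84 and 6.32), PHT3;2 (0.0410, 11.3, 12.0 and 20.2) and HSP23.6-MITO (0, 4.23, 5.71 and 5.63). TIR was at 29.6, 14.4 and 10.8 in the first 3 of these groups. Mock-sprayed 35S::STM-GR had all 7 nearer to DEX-sprayed than to unsprayed wild type, so their differing response came with the unsprayed reference of wild type. Outside the genes, reads that met no annotated gene made up 0.716% in DEX-sprayed wild type against 0.656% in unsprayed wild type, and 0.756% against 0.688% for DEX and mock in 35S::STM-GR. Reads that met more than 1 gene made up 1.61% in DEX-sprayed wild type against 1.58% in unsprayed wild type. In each of these 3 cases every DEX library lay above every library it was set against. No group had the 4 libraries that a test for a stray sample needs.

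The 105 genes that rose in DEX-sprayed wild type could reflect dexamethasone itself, or spray, handling or harvest shared by all sprayed plants. Dexamethasone itself was excluded as the main cause, since mock-sprayed 35S::STM-GR, which received none, had these genes higher than ap1-1 by a median log2 difference of 2.22 (quartiles 1.12 to 4.00). In wild type the median was 2.31. On DEX against mock in 35S::STM-GR the median of these genes was 0.35, so a smaller part from dexamethasone stays open. Of the 105 genes, 101 were also called higher in mock-sprayed 35S::STM-GR than in ap1-1, 96.2% against 13.6% of all genes tested, as shared spray or handling predicts. ABCB4, chosen after its values were seen, was at 4.46 CPM in unsprayed wild type, 94.5 with DEX and 122 with mock spray in 35S::STM-GR. Its mock replicates 1 to 3 were at 89.7, 194 and 83.5 CPM. A high mock replicate 2 can lower the median of 0.35. Without that replicate, genes that rose in both DEX responses went from 25 to 75.

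For induction, the 6 STM-GR libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2760 genes and the highest other 0, so 1 of 10 splits gave as many.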

How the results depend on the processing

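The microRNA line against wild type, and DEX-sprayed wild type against mock-sprayed 35S::STM-GR, were tests chosen only after the results were seen. Every call rests on 2 or 3 libraries per group. For single genes the alternatives were DESeq2, size factors, no filter, the block by title number, only the groups compared and each library left out. Of the genes singled out by rule and called, 46 of 70 (silencing), 54 of 68 (induction), 4 of 14 (DEX in wild type), 19 of 32 (the differing response) and 21 of 68 (ap1-1 against wild type) kept the call in every alternative, while 23, 14, 10, 13 and 36 lost it without 1 library and 16, 3, 7, 3 and 47 elsewhere. Only WRKY40 in ap1-1 against wild type turned direction, with log2 fold changes from -3.17 to 0.0722 without 1 library (the last without wild-type replicate 2). No limma-voom fit, other scaling, other filter or use of the normalized values moved the number of genes called in a comparison by over 1.5 times, and neither did testing induction against DEX-sprayed wild type. The genes called did change in that last test: of the 2760 induction calls, 1718 were called in the same direction there. Counts of list members called moved more between tools, as the report gives. At this depth a floor of 3 counts was 0.113 to 0.160 CPM in 1 library. A stricter threshold lowers a count by construction. For the other changes below the cause was not tested. Replicates of unsprayed wild type and ap1-1 were less alike than others. With the spread shared over all groups, p-values for silencing and for ap1-1 against wild type may thus be too small.

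Genes that rose and fell, with a minimum change of 2-fold, numbered 118 and 1332 (silencing), 207 and 188 (induction), 86 and 7 (DEX in wild type), 98 and 121 (the differing response) and 261 and 257 (ap1-1). At an adjusted p of 0.01 they were 430 and 1574 (silencing), 586 and 700 (induction), 60 and 9 (DEX in wild type), 102 and 80 (the differing response) and 392 and 476 (ap1-1), and with only the groups compared in the fit 344 and 1603 (silencing), 2262 and 2792 (induction), 60 and 6 (DEX in wild type), 348 and 373 (the differing response) and 94 and 140 (ap1-1). DESeq2 gave 166 and 80 for DEX in wild type, and 340 lower differing responses. In these later tests the microRNA line against wild type gave 2631 and 3652, and DEX-sprayed wild type against mock-sprayed 35S::STM-GR 3 and 4. Of the 3532 silencing calls, 2761 were called in the same direction in the microRNA line against wild type.

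Overlaps of induction and silencing, in the order rose then fell, fell then rose, rose in both and fell in both, were 16, 10, 3, 18 at 2-fold, 78, 57, 29, 52 at an adjusted p of 0.01 and 253, 91, 49, 138 with only the groups compared. Genes that rose in both and fell in both DEX responses numbered 49 and 38 (DESeq2), 3 and 1 (2-fold), 4 and 0 (adjusted p of 0.01) and 12 and 3 (only the groups compared); the 0 was edgeR's, with 13 at 0.05. With an estimated correlation 0 lists passed camera in any comparison, and 3, 4, 1, 4 and 2 had an unadjusted p under 0.05 (in the order above).

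Leaving out each library in turn, genes that rose and fell numbered 318 to 1296 and 1332 to 2756 (silencing), 657 to 1110 and 809 to 1403 (induction), 38 to 158 and 1 to 104 (DEX in wild type), 95 to 276 and 100 to 207 (the differing response) and 392 to 1855 and 599 to 1775 (ap1-1). The 4 overlaps of induction and silencing were 120 to 307, 66 to 288, 26 to 107 and 76 to 240, and those of the DEX responses 3 to 75 and 0 to 21.

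The replicate numbers did not pair the libraries, with correlations of deviations from the group mean of -0.128 to 0.0765. The replicate block by title number gave 887 and 2302 (silencing), 1165 and 1519 (induction), 107 and 33 (DEX in wild type), 203 and 210 (the differing response) and 1106 and 1129 (ap1-1), and by description number 855 and 2268 (silencing), 1085 and 1420 (induction), 73 and 11 (DEX in wild type), 170 and 150 (the differing response) and 1002 and 1058 (ap1-1). The replicate block in a fit of the 6 STM-GR libraries gave 1991 and 2489 for induction. With the block by description number 15 genes rose and 3 fell in both DEX responses, and with that by title number 1 list was lower for DEX in wild type.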

Other observations

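The lists of anthocyanin, histone and plastid-encoded genes and the tests of the ap1-1 mutation, RNA-directed DNA methylation, whole anthers and old buds were chosen only after the results were seen. Of the genes of anthocyanin and flavonol synthesis, on silencing 8 of 14 rose and 1 fell (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.96e-05, and adjusted p = 0.0800 with an estimated correlation). On induction 2 of 14 rose and 7 fell (2 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.0326, and adjusted p = 0.569 with an estimated correlation). Of histone genes in DEX-sprayed wild type 12 of 42 fell (1 rose and 28 fell adjusted over the list alone; camera adjusted p = 1.71e-23, and adjusted p = 0.0916 with an estimated correlation). Near-identical copies of histone genes can share reads. Of genes encoded in the plastid, in ap1-1 against wild type 19 of 65 rose (35 rose adjusted over the list alone; camera adjusted p = 4.06e-14, and adjusted p = 0.307 with an estimated correlation). On silencing 10 of 65 fell (11 fell adjusted over the list alone; camera adjusted p = 5.76e-04, and adjusted p = 0.388 with an estimated correlation). Plastid-encoded genes made up 0.0203%, 0.0144% and 0.0353% of gene counts in ap1-1 replicates 1 to 3 and 0.00815% and 0.0108% in wild type. For genes encoded in mitochondria it was 0.0264%, 0.0192% and 0.0350% and 0.0121% and 0.0157%, and reads with more than 1 alignment made up 4.23%, 3.61% and 4.38% and 3.25% and 3.61%.

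A set of 19 genes was at least 2-fold lower in ap1-1 than in both wild type and the microRNA line, which shares the ap1-1 allele. It held genes of glucosinolate and methionine-chain metabolism, with log2 fold changes for ap1-1 against wild type and for the microRNA line against ap1-1 of FMO GS-OX1 (-2.39 and 1.82), GSTF11 (-2.16 and 1.66), BAT5 (-2.10 and 1.40), IMD1 (-1.51 and 1.24), IPMI2 (-1.30 and 1.15) and MYB29 (-1.51 and 1.22). They were picked out of the set by eye, with no test of enrichment. Of 16 other genes of the RNA-directed DNA methylation machinery, a list also chosen after, edgeR called 0 in ap1-1 against wild type, with 6 at an unadjusted p under 0.05 and camera adjusted p = 0.0831, and adjusted p = 0.457 with an estimated correlation. Mock-sprayed 35S::STM-GR and DEX-sprayed wild type differed in 7 genes. STM was at 51.5 CPM in the sprayed wild type against 814 CPM in mock-sprayed 35S::STM-GR, and the log2 differences of wild type from it were STM (-3.98 ± 0.09), MUB5 (-2.43 ± 0.25), OLEO4 (-0.85 ± 0.13), AT1G22160 (-0.82 ± 0.10), PRR5 (0.55 ± 0.08), AT1G62305 (0.59 ± 0.08) and FKF1 (0.61 ± 0.08).

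NRPD1B (the largest subunit of RNA polymerase V, also NRPE1) and DML1 (the DNA demethylase ROS1) were low in ap1-1 alone, and the ap1-1 mutation, a variant region on chromosome 2 or lower RNA-directed DNA methylation could be involved. The mutation did not keep both genes low in the microRNA line, which carries it. There the lower of the 2 log2 differences from wild type was -0.201 ± 0.109 (DML1). That line also differs from ap1-1 by the microRNA, and possibly by stock, so an effect of the mutation in the ap1-1 plants is not excluded. Between the 2 loci, 0 of the 17 other genes low in ap1-1 alone were found among 324 genes tested, where 0.254 were expected, so the region stays open because too few such genes exist. SDC, a gene that RNA-directed DNA methylation silences, was 1.92 ± 0.348 log2 higher in ap1-1 than in wild type (edgeR adjusted p = 0.00316) and lower in the microRNA line than in ap1-1 (-1.62 ± 0.35, 0.00481), as lower methylation predicts. Its level was 1.41 CPM in ap1-1 and 0.371 CPM in wild type, but also 0.830 ± 0.197 CPM with DEX against 0.489 ± 0.208 CPM with mock in 35S::STM-GR, where NRPD1B was not low (121 CPM with mock), and DNA methylation itself was not measured.

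The 1332 genes at least 2-fold lower after silencing could reflect lower sequencing depth, loss of whole anthers or fewer old flower buds in the tissue. A difference in stock between the microRNA line and ap1-1, which the labels leave open, was not tested. Depth was excluded: 1262 (94.7%) stayed at least 2-fold lower with every library thinned to the smallest total. The tapetum and pollen wall list, which loss of whole anthers would lower, had a median log2 change of 0.116 (quartiles -0.135 to 0.275). This argues against loss of anthers at the stages that these genes mark. It cannot decide on loss of older anthers, and mature pollen genes did fall. Fewer old buds cannot be told apart from an effect of genotype. These genes also varied among ap1-1 libraries, with a median log2 difference of -0.411 between replicate 2 and the others. Replicate 2 was picked as the ap1-1 library nearest to the microRNA line on the first principal component. That choice favours a negative value, so the value cannot decide the question. Against wild type the medians were -0.469 in that library and -2.03 and -2.10 in the microRNA libraries.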
